A study of Mus musculus with 4 samples.

How the data were processed

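Total RNA from 4 mouse embryonic stem (ES) cell clones, 2 wild-type (WT) and 2 in which the gene of the transcription factor Klf5 was knocked out (KO), was hybridised to Affymetrix GeneChip arrays, 1 array per clone. Embryonic stem cells are cells of the early embryo that multiply in culture and keep the ability to form all tissues. Per the labels' protocols, the cells grew in ES medium with serum and LIF, the cytokine that keeps mouse ES cells undifferentiated, RNA was purified on silica columns and labelled with biotin after the manufacturer's manual, and nothing in the labels names a feeder layer. The 4 arrays were grouped by their titles, and the clones of a group were taken as its 2 replicates. The labels call them separate clones. Whether their cultures were run in parallel, and on which day each array was hybridised, is not given in the sources used here.

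The deposited table holds 1 intensity per probe set and array on a linear scale (45101 rows, 64 of them control probe sets). The algorithm that summarised the probes, the background correction and any scaling are not given in the sources used here. The intensities run from 0.0168 to 14472, and the deposited arrays differ in level by up to 1.65 times in their trimmed mean (2% removed at each end), with WT clone 1 brightest. No further background was subtracted. No detection calls were used. Because the trimmed means differed by more than the 5% set before the data were examined, the arrays were quantile normalized (limma 3.58.1 in R 4.3.3), and log2(intensity + 16) was taken. Fold changes are on this scale, which understates the change of dim genes. Normalization makes all changes relative to the bulk of the probe sets, so a shift common to most of them would not be seen.

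Control probe sets were left out of the tests. Probe sets with a mean log2 value over the 4 arrays below the 40th percentile were removed, which left 27022. A linear model with moderated variance (limma lmFit and eBayes, 2 residual and 6.87 prior degrees of freedom) compared KO with WT, and p-values were adjusted over all kept probe sets (Benjamini-Hochberg), with 0.05 as the threshold. Errors are the moderated standard error (SE) of the log2 fold change, with n = 2 arrays per group throughout. The number of arrays limits the precision. Probe sets were named with the platform annotation. Of all rows, 34958 had 1 gene symbol, 932 had several and 9160 non-control rows had none, and the gene IDs of 34754 matched the mouse reference gene table (GRCm38.p6), which changed no symbol. Rows with several genes or none were tested but are not named. Each gene was represented by its probe set of highest mean, one with the suffix _x_at only where there was no other, which gave 13023 genes.

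A second criterion without a test counted probe sets at least 2-fold apart, with one sign, in all 4 pairings of a KO clone with a WT clone. The submitters state that genes lower in KO were searched with GeneSpring software; no threshold is given in the sources used here. A total of 24 gene lists fixed before the data were examined were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. A list was also tested with a correlation estimated from the data and with fry, which tests whether its genes move, on balance, one way and does not compare them with other genes. These lists covered the Kruppel-like factors, pluripotency, the LIF, AKT, FGF and Nodal pathways, the post-implantation epiblast, primitive endoderm, trophectoderm, mesoderm, neural and germ cells, fibroblasts and feeder cells, mesenchymal, epithelial, cell cycle and p53 genes, glycolysis, cholesterol synthesis, stress, interferon, imprinted, Y-linked and ribosomal protein genes.

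The genes named were chosen by a rule fixed before the data were examined: Klf5, the 12 largest rises and the 12 largest falls among genes past the threshold with all 4 clone pairings of one sign, up to 4 members of each list (the 2 largest each way past the threshold, filled by size where fewer than 2 passed), and Pou5f1, Sox2, Nanog, Tcl1, Klf2, Klf4 and Cdx2. This gave 77 genes. Of these, 32 had more than 1 kept probe set, and none had another probe set past the threshold in the opposite direction. For 8 genes that passed (1700097N02Rik, Cdh2, Dazl, Fosl1, Klf5, Krt42, Lamc1 and Ndn) another probe set did not pass, and 2 genes (1700097N02Rik and Pfkl) had one of opposite sign. A gene named outside the rule is marked as chosen after its values were seen.

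The alternatives were a pseudocount of 1 or 64, no filter or a filter at the 60th percentile, no between-array normalization, centring on the median, a variance prior with a trend, the clone number as a block, each array left out in turn (the lone array of the group was then assumed to vary like the other group), the mean of a gene's probe sets, and fold criteria of 1.5 and 3. Centring on pluripotency genes and lists without fibroblast or mesenchymal genes were added after seeing the data. The model was run on 20 simulated data sets of 27022 probe sets with 200 changed. Means were those of this comparison, and spreads were drawn, independently per probe set, from the variance prior that limma had fitted. The model recovered 97.8% of log2 changes of 2 and 21.6% of log2 changes of 1, and 5.83% of its calls were false. Such data meet the model's own assumptions, so a share of false calls near the threshold was largely set in advance. In simulated lists of independent genes, camera found a list of 20 genes shifted by 0.5 in every data set with the preset correlation. With an estimated correlation it found the list in 0%. In this design, failing at that setting therefore does not show that a list is unshifted. This holds for every such p-value given below. The correlations estimated for the real lists ran up to 0.41, which the simulated lists did not have. With 2 arrays against 2, an exact permutation test cannot give a two-sided p under 0.33, so single values outside the model carry no p-value.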

Results

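The data were genome-wide expression profiles of mouse ES cells with and without the zinc finger transcription factor Klf5, measured on 1 Affymetrix array per clone in 2 WT and 2 Klf5 KO clones. The stated purpose was to find genes that were lower in the KO cells. The trimmed mean of the deposited intensities was 227 in WT clone 1, 139 in WT clone 2, 138 in KO clone 1 and 150.5 in KO clone 2. After normalization, the correlation across probe sets was 0.986 between the WT clones and 0.984 between the KO clones, and it ranged from 0.961 to 0.973 between WT and KO clones. The log2 ratio of the 3′ to the 5′ control probe set of beta-actin, a sign of RNA quality, was 0.40 and 0.49 in WT clones 1 and 2 and 0.79 and 0.55 in KO clones 1 and 2. That of Gapdh was -0.28 and -0.36 in WT and -0.36 and -0.30 in KO.

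Klf5 itself was the gene with the largest fall. Its brightest probe set had a normalized intensity of 2399 and 1782 in WT clones 1 and 2 against 34.8 and 49.9 in KO clones 1 and 2. The log2 value fell by 5.17 ± 0.22 (SE, n = 2 arrays per group; limma, adjusted p = 3.3e-05), a 36.0-fold difference. Another, dimmer probe set read 102 and 88.6 in WT and 82.6 and 61.0 in KO, with a log2 fold change of -0.35 ± 0.20 that did not pass the threshold (adjusted p = 0.36). The remaining one was removed by the filter on dim probe sets. The files do not say which part of the gene was deleted or which part each probe set covers. The brightest probe set separated the WT from the KO arrays as labelled. The limma p-values here rest on the spread between clones as labelled, with 2 clones per group, moderated by a prior fitted over all kept probe sets. Camera's p-values with the preset correlation compare the genes of a list with the other genes. They do not measure the spread between clones.

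More genes were higher than lower without Klf5. Of 27022 probe sets, 659 were higher and 337 lower in KO clones (996 in all, limma, adjusted p under 0.05), which came to 383 genes higher and 175 lower of 13023. By size, 290 of the higher genes and 93 of the lower genes changed by at least 2-fold. By the fold criterion alone, 302 probe sets were at least 2-fold higher and 67 at least 2-fold lower in every pairing of a KO with a WT clone, 369 in all. The other 2 ways of splitting the 4 arrays into pairs, which mix the genotypes, gave 5 and 5 such probe sets. By limma they gave 0 and 0 past the threshold (401 and 276 at an unadjusted p under 0.05, against 5508 for KO against WT). In these splits any difference between KO and WT lies inside the groups and widens their spread. Low counts were therefore largely built in, and they are not a chance level for the KO against WT counts. The count of calls fell with any array left out: to 653 without WT clone 1, 489 without WT clone 2, 203 without KO clone 1 and 353 without KO clone 2. It was 189 with a pseudocount of 1 and 2060 with one of 64. Of the 61 named genes that passed, 29 passed in every leave-out of 1 array in which they were measured, and 25 passed under every alternative processing in which they were measured.

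The 12 largest falls, Klf5 included, were ranked with a pseudocount of 16, and the order depends on it. Tgm1, a transglutaminase that cross-links the envelope of keratinocytes, fell by 2.72 ± 0.26 on the log2 scale (adjusted p = 0.00087). Mras, a small GTPase related to Ras, fell by 2.44 ± 0.19 (adjusted p = 0.00031), Gpx2, an epithelial glutathione peroxidase, by 2.10 ± 0.22 (adjusted p = 0.0016; with a pseudocount of 1 it had -3.69, beyond the -3.26 of Tgm1, with adjusted p = 0.091), and Stmn2, a microtubule regulator best known from neurons, by 2.08 ± 0.19 (adjusted p = 0.00063). Bcam, a laminin receptor, fell 3.95-fold, the laminin chain gene Lama1 fell 3.36-fold, and the uncharacterised transcript 1700097N02Rik fell 3.85-fold. Hsd17b14, a steroid dehydrogenase, fell 3.43-fold, the septin gene Septin1 3.31-fold, and the keratin gene Krt42 3.21-fold, although a brighter probe set of Krt42 (suffix _x_at) had a log2 fold change of -0.60 (adjusted p = 0.15). A further probe set of 1700097N02Rik, dim, had 0.0072 (adjusted p = 0.99). Klf12, a transcription factor of the same family as Klf5, fell 3.27-fold (adjusted p = 0.013) on a probe set whose suffix (_s_at) marks probes that can also match related transcripts. Dimmer Klf12 probe sets without that suffix also passed by limma, at -1.65 (adjusted p = 0.0022) and -1.21 (adjusted p = 0.018) on the log2 scale. Tgm1, Mras, Stmn2, Bcam, 1700097N02Rik and Lama1 passed under every alternative processing. Without KO clone 1, Hsd17b14, Septin1, Krt42 and Klf12 no longer passed (adjusted p = 0.072, 0.073, 0.082 and 0.088), and Klf12 also failed without KO clone 2 (adjusted p = 0.090).

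The other Kruppel-like factors did not pass one by one, apart from Klf12. Of the 15 measured family members other than Klf5, 0 rose, 1 fell and 14 did not pass (4 fell when adjusted over the list alone). Klf2 and Klf4, both expressed in ES cells, had log2 fold changes of -0.33 (95% confidence interval -0.77 to 0.11) and 0.074 (-0.43 to 0.57), and the sign for Klf4 turned negative in the values as deposited (-0.22), after centring on the median (-0.024), without WT clone 2 (-0.16) and without KO clone 2 (-0.070). Klf15 had -1.14 ± 0.28 (adjusted p = 0.065), and -0.76 without KO clone 2. The family's median was -0.26 (camera, adjusted p = 0.033, and adjusted p = 0.45 with an estimated correlation), beside 1.91 for genes of fibroblasts, and this call was lost with any one of the 4 arrays left out (adjusted p from 0.056 without KO clone 2 to 0.15 without WT clone 1).

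**Figure D1:**
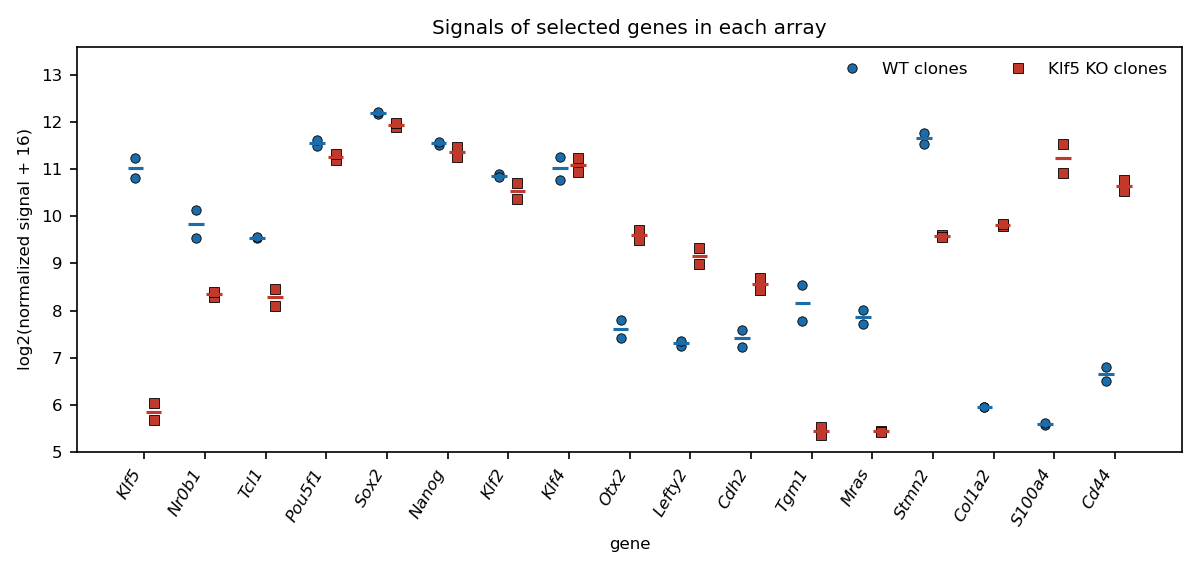
Log2 of the normalized intensity plus 16 (vertical axis) for 17 genes (horizontal axis); circles are the 2 WT clones, squares the 2 Klf5 KO clones, and bars the group means. Klf5, Nr0b1, Tcl1, Tgm1, Mras and Stmn2 are lower in both KO clones and passed the threshold. Pou5f1, Sox2, Nanog and Klf2 are also lower in both KO clones, by less, and did not pass. Otx2, Lefty2, Cdh2, Col1a2, S100a4 and Cd44 are higher, and the clones of both groups overlap for Klf4.

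The list of pluripotency genes had a median of -0.18 (camera, adjusted p = 0.014). With an estimated correlation, camera gave adjusted p = 0.52. At that setting 0 lists passed, and simulated lists with a true shift were found in 0% of data sets. This value therefore cannot weigh for or against the list. The test fry, which asks whether the genes move one way and does not compare them with other genes, gave adjusted p = 0.12. Of 39 measured genes of the list, 0 rose, 2 fell and 37 did not pass (3 fell when adjusted over the list alone). Without regard to the test, 21 of the 39 were lower and 4 higher in both KO clones than in both WT clones. Chance alone separates the groups, in either direction, for 33% of genes, but the share over all genes is not given here. Lists that did not pass had such genes too: 15 lower and 7 higher of 29 trophectoderm genes, and 11 and 6 of 24 stress genes. For 25 glycolysis genes it was 9 and 2. This count alone therefore does not set the pluripotency list apart. The genes that fell were Nr0b1 (Dax1), a nuclear receptor expressed in ES cells, by 1.497 ± 0.23 on the log2 scale (2.82-fold, adjusted p = 0.0095), and Tcl1, a co-activator of the kinase AKT, by 1.27 ± 0.20 (2.41-fold, adjusted p = 0.010). The core factors did not pass: Pou5f1 (Oct4) had -0.30 (95% confidence interval -0.71 to 0.11), Sox2 -0.25 (-0.66 to 0.15) and Nanog -0.18 (-0.59 to 0.24). Each of these core factors read lower in both KO clones than in both WT clones. Cdx2, the trophectoderm factor, had -0.34 (-0.77 to 0.09). Fibroblast genes had a median of 1.91 in the same comparison. By camera with the preset correlation, the pluripotency list passed with each array left out (adjusted p from 0.016 to 0.022). Without KO clone 1, Nr0b1 and Tcl1 no longer passed (adjusted p = 0.11 and 0.097), and Nr0b1 failed without KO clone 2 as well (adjusted p = 0.064).

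The AKT and LIF pathways help to maintain ES cells. Of 18 AKT pathway genes, 1 fell (Tcl1) and 17 did not pass (2 fell when adjusted over the list alone), with Irs2, an insulin receptor substrate, at -0.93 ± 0.33 (adjusted p = 0.15), a value that was -0.36 without KO clone 1 and -1.52 without KO clone 2. The list's median was -0.31 (camera, adjusted p = 0.027, and adjusted p = 0.62 with an estimated correlation), beside 1.91 for fibroblast genes, and its call was lost without KO clone 1 (median -0.14, adjusted p = 0.20) and with the stricter filter (adjusted p = 0.054). Of 20 LIF and STAT3 response genes, Osmr, a cytokine receptor subunit, rose by 1.11 ± 0.18 (adjusted p = 0.014), Gbx2, a homeobox factor, fell by 0.94 ± 0.19 (adjusted p = 0.032), and 18 did not pass (3 rose and 3 fell when adjusted over the list alone). That list did not pass (median -0.069, camera, adjusted p = 0.62). In WT clones Osmr read 12.1 and 9.97, under the filter intensity of 13.05. Its log2 fold change ran from 0.50 to 1.85 over the alternatives. Gbx2 failed with any array left out (adjusted p from 0.057 to 0.17), and Osmr without WT clone 2, KO clone 1 or KO clone 2 (adjusted p from 0.066 to 0.083).

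Of the 12 largest rises in KO clones, 3 (S100a4, Col1a2 and Bgn) were on the list of fibroblast and feeder cell genes. S100a4, a calcium-binding protein used as a fibroblast marker, rose by 5.64 ± 0.23 on the log2 scale (50.03-fold, adjusted p = 3.3e-05), Cdh11, a mesenchymal cadherin, by 4.36 ± 0.20 and the membrane protein gene Tm4sf1 by 4.35 ± 0.23. Tnc (tenascin-C, a matrix protein) rose 16.1-fold, Cd44 (a hyaluronan receptor) 16.01-fold, Col1a2 (a chain of type I collagen) 14.6-fold and Ptgs2 (cyclooxygenase 2) 12.8-fold. The proteoglycan Bgn rose 12.7-fold, the BMP antagonist Grem1 12.6-fold and the secreted serpin Serpinf1 10.2-fold, and on the log2 scale the protease inhibitor Serpinb2 rose by 3.67 ± 0.26 and the caveola gene Cavin2 by 3.50 ± 0.23. In WT clones Cdh11, Tm4sf1, Serpinb2 and Cavin2 read 2.40 to 17.0, near the intensity of 13.05 at which the filter was set, so their sizes and ranks depend on the pseudocount. Over the alternatives their log2 fold changes ran from 3.07 to 5.37, from 3.01 to 5.46, from 2.15 to 5.70 and from 2.25 to 4.63. All 12 passed under every alternative processing.

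Of 27 measured genes on the list of fibroblast and feeder cell genes, 26 rose, 0 fell and 1 did not pass (26 rose when adjusted over the list alone). Their median log2 fold change was 1.91 (camera, adjusted p = 3e-39, and adjusted p = 0.19 with an estimated correlation), at 1.90 in KO clone 1 and 1.97 in KO clone 2 against the WT mean. Of 17 mesenchymal genes, 6 rose and 11 did not pass (13 rose when adjusted over the list alone), with a median of 0.78 (camera, adjusted p = 6.9e-09, and adjusted p = 0.45 with an estimated correlation). Among these, S100a6, a calcium-binding protein, rose 3.43-fold and Axl, a receptor tyrosine kinase, 3.35-fold. Both lists kept their calls with each array left out, while S100a6 failed without KO clone 1 (adjusted p = 0.063), with no filter (0.062) and with a pseudocount of 1 (0.074), and Axl with a pseudocount of 1 (0.052).

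Of 16 measured genes of the post-implantation epiblast, the tissue that follows the ES cell stage in the embryo, 3 rose and 13 did not pass (6 rose when adjusted over the list alone). Otx2, a homeobox factor of the epiblast and anterior brain, rose by 2.00 ± 0.20 (4.002-fold, adjusted p = 0.0013), and Cdh2 (N-cadherin), which fibroblasts also express, by 1.15 ± 0.21 (2.22-fold, adjusted p = 0.020), although its other probe set had 0.54 (adjusted p = 0.18). The third, Fgf5, was named after its values were seen: it rose by 1.11 ± 0.20 (adjusted p = 0.019), to a low intensity of 34.3 and 28.1. The list's median was 0.33 (camera, adjusted p = 0.0080, and adjusted p = 0.45 with an estimated correlation), beside 1.91 for fibroblast genes. Its call was lost without KO clone 2 (median 0.25, adjusted p = 0.089), and fry, a test of another hypothesis, gave adjusted p = 0.12. Otx2 passed under every alternative processing, while Cdh2 failed without WT clone 2, KO clone 1 or KO clone 2 (adjusted p = 0.10, 0.097 and 0.095).

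Among Nodal response genes, the Nodal antagonists Lefty1 and Lefty2 rose and Bmp4 fell. Of 12 measured, 2 rose, 1 fell and 9 did not pass (3 rose and 2 fell when adjusted over the list alone). Lefty2 rose by 1.86 ± 0.19 (3.62-fold, adjusted p = 0.0015), its close paralog Lefty1, whose transcript can cross-hybridise, by 0.90 ± 0.19 (adjusted p = 0.041), and Bmp4, a growth factor, fell by 1.17 ± 0.21 (2.25-fold, adjusted p = 0.018). The list as a whole did not pass (median 0.073, camera, adjusted p = 0.35). Of 19 FGF and ERK response genes, Fosl1, an AP-1 factor, rose by 1.10 ± 0.18 (adjusted p = 0.015, but 0.13 with adjusted p = 0.79 on its other, dimmer probe set), Spred1, an inhibitor of ERK signalling, fell by 1.09 ± 0.20 (adjusted p = 0.020), and 17 did not pass (2 rose and 2 fell when adjusted over the list alone). Here the median was -0.13, the mean 0.017 and camera's direction higher (adjusted p = 0.85). Lefty2 passed under every alternative processing. Lefty1 and Fosl1 failed with any array left out (adjusted p from 0.090 to 0.15 and from 0.051 to 0.12), Bmp4 in all leave-outs but that of WT clone 1 (highest adjusted p = 0.10) and Spred1 in all but that of WT clone 2 (highest adjusted p = 0.15).

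**Figure D2:**
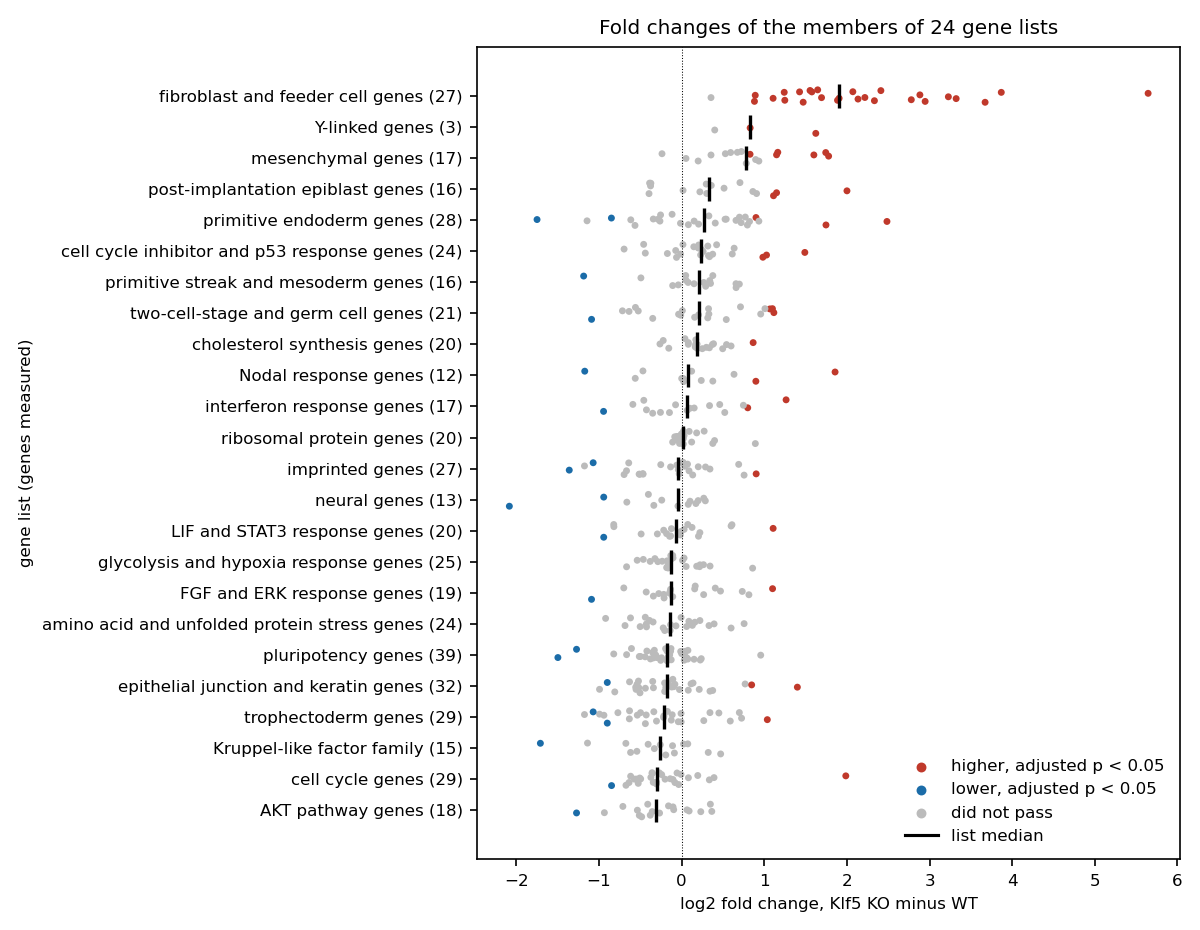
Log2 fold change of KO over WT (horizontal axis) for every measured member of 24 gene lists (vertical axis, number of genes in brackets); each point is a gene, coloured where its adjusted p passed, and black bars are list medians. The 27 fibroblast and feeder cell genes have a median of 1.91, while the 39 pluripotency genes have one of -0.18.

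No list of another early lineage passed as a whole, and members moved in both directions. Of 28 primitive endoderm genes, 3 rose, 2 fell and 23 did not pass (9 rose and 5 fell when adjusted over the list alone; median 0.27, camera, adjusted p = 0.056). Fst, the activin inhibitor follistatin, rose by 2.48 ± 0.20 (5.60-fold, adjusted p = 0.00034) and Thbd, thrombomodulin, by 1.75 ± 0.18 (3.36-fold, adjusted p = 0.0015), in the same arrays in which fibroblast genes were higher by a median of 1.91. The laminin genes Lama1 and Lamc1 fell, by 1.75 ± 0.19 and 0.85 ± 0.19, and a dimmer probe set of Lamc1 had -0.53 (adjusted p = 0.28). This list passed by camera in the values as deposited (adjusted p = 0.036) and after centring on the median (0.039). It also passed with the stricter filter (0.029), with a variance trend (0.042) and without WT clone 1 (median 0.28). With an estimated correlation, camera gave it adjusted p = 0.45. Of 29 trophectoderm genes, 1 rose, 2 fell and 26 did not pass (3 rose and 5 fell when adjusted over the list alone; median -0.22, camera, adjusted p = 0.077). Lgals1, a galectin also made by fibroblasts, rose by 1.04 ± 0.18 (adjusted p = 0.016), while Peg10, a placental gene, fell by 1.07 ± 0.19 (adjusted p = 0.020) and the keratin Krt18 by 0.90 ± 0.19 (adjusted p = 0.038). That list passed by camera without WT clone 1 (median -0.29) and without KO clone 2 (-0.41). It also passed with no filter (adjusted p = 0.044), with the mean of a gene's probe sets (0.035) and with clone number as a block (0.0499). With an estimated correlation, camera gave it adjusted p = 0.62.

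Of 16 primitive streak and mesoderm genes, Meox1, a homeobox factor of somites, fell by 1.19 ± 0.22 (adjusted p = 0.025). Meox1 read 2.40 and 10.6 in KO clones, under the filter intensity of 13.05. Over the alternatives its log2 fold change ran from -2.49 to -0.48. The other 15 did not pass (1 rose and 1 fell when adjusted over the list alone), among them Hand1 at 0.70 ± 0.19 (adjusted p = 0.085). The list did not pass (median 0.21, camera, adjusted p = 0.26). Of 13 neural genes, Stmn2 and Gbx2 fell and 11 did not pass (3 fell when adjusted over the list alone; median -0.044, adjusted p = 0.17). Lamc1, Krt18 and Peg10 failed with any array left out (highest adjusted p = 0.23, 0.21 and 0.14), Lgals1 in all leave-outs but that of WT clone 1 (highest adjusted p = 0.12) and Meox1 without KO clone 1 (adjusted p = 0.16).

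The list of epithelial genes did not pass. Of 32 epithelial junction and keratin genes, 2 rose, 1 fell and 29 did not pass (3 rose and 3 fell when adjusted over the list alone; median -0.18, camera, adjusted p = 0.077). Pkp1, a desmosomal plaque protein, rose by 1.40 ± 0.25 (adjusted p = 0.019), Marveld3, a tight junction protein, by 0.85 ± 0.19 (adjusted p = 0.043), and Krt18 fell. At an unadjusted p under 0.05 there were 14 of the 32, beside 5508 of all 27022 probe sets. In both KO clones, 18 were lower and 5 higher than in both WT clones. The share over all genes for this last measure is not given here, so that count does not set the list apart. This list passed by camera without KO clone 2 (median -0.34), with a pseudocount of 1 (adjusted p = 0.039) and with no filter (0.045). With an estimated correlation, camera gave it adjusted p = 0.62. Pkp1 was too dim for the filter when either KO clone was left out, and failed with no filter (adjusted p = 0.12), and Marveld3 failed with any array left out (adjusted p from 0.081 to 0.20). Of 29 cell cycle genes, Ccnd2 (cyclin D2) rose by 1.99 ± 0.20 (3.96-fold, adjusted p = 0.0011), the proliferation marker Mki67 fell by 0.85 ± 0.18 (adjusted p = 0.035), and 27 did not pass (1 rose and 1 fell when adjusted over the list alone). The list's median was -0.30 (camera, adjusted p = 0.015, and adjusted p = 0.62 with an estimated correlation), beside 1.91 for fibroblast genes, with adjusted p = 0.065 without WT clone 1. Mki67 failed with any array left out (adjusted p from 0.098 to 0.17), while Ccnd2 passed under every alternative processing.

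Of 24 cell cycle inhibitor and p53 response genes, 3 rose and 21 did not pass (5 rose and 1 fell when adjusted over the list alone). Cdkn1a (p21), an inhibitor of cyclin-dependent kinases, rose by 1.49 ± 0.18 (2.81-fold, adjusted p = 0.0030) and Cdkn2b (p15) by 1.03 ± 0.22 (2.04-fold, adjusted p = 0.039). The list's median was 0.23 (camera, adjusted p = 0.024, and adjusted p = 0.52 with an estimated correlation), beside 1.91 for fibroblast genes. In the values as deposited, where the median of all probe sets was -0.19, the list's median was -0.0078 and its call was lost (adjusted p = 0.13), as it was after centring on the median (0.093), with the stricter filter (0.066) and without WT clone 2 (0.15). Cdkn1a failed with a pseudocount of 1 (adjusted p = 0.053) and in the values as deposited (0.10), and Cdkn2b failed without WT clone 2, KO clone 1 or KO clone 2 (highest adjusted p = 0.20).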

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

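The centring on pluripotency genes and the lists without fibroblast and mesenchymal genes were chosen after seeing the data. Klf5 stayed lower and past the threshold under every alternative, from -5.39 to -4.88 with an array left out. The count of changed probe sets (996; 659 higher, 337 lower) was 189 (160 and 29) with a pseudocount of 1, 2060 (1145 and 915) with one of 64, 190 (164 and 26) with no filter, 332 (215 and 117) in the values as deposited, 1955 (1118 and 837) with a variance trend and 558 (383 and 175) over genes. With the filter at the 60th percentile, 615 were lower. With an array left out it ranged from 203 to 653 (169 to 530 higher, 34 to 123 lower), where fewer arrays were tested. After centring on pluripotency genes, which moved the median of all probe sets to 0.21, it was 1927 (1778 and 149), so the share of higher calls went from 66.2% to 92.3%. The count at least 2-fold apart in every clone pairing (369; 302 higher, 67 lower) was 619 (457 and 162) with a pseudocount of 1, 166 (143 and 23) with 64, 1284 (796 and 488) at 1.5-fold and 133 (121 and 12) at 3-fold, 187 higher in the values as deposited, 474 higher and 37 lower after centring on pluripotency genes, and 534 to 789 (378 to 536 higher, 108 to 253 lower) with an array left out, which leaves fewer pairings to satisfy. The prior degrees of freedom fell from 6.87 to 3.23 with a pseudocount of 1 and 3.66 with no filter, and rose to 8.26 with one of 64. They were 30.0 after centring on pluripotency genes and infinite in the values as deposited, where all probe sets then share the same variance. Counts under these 2 settings are therefore not like for like with the main fit. For these changes the cause was not tested, apart from the leave-outs, which have fewer arrays.

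Between 8 and 12 of the 24 lists passed under the other alternatives, against 10, but 0 passed with an estimated correlation (camera, with 1 at an unadjusted p under 0.05) and 1, the fibroblast list, with fry, which does not compare a list with other genes. Simulated lists of independent genes with a true shift were found in 0% of data sets with an estimated correlation in this design. The clone numbers share nothing that the labels record, and the deviations of same-numbered clones correlated at 0.055. With the clone number as a block, 1390 probe sets passed (891 higher, 499 lower), among them the probe sets of all 558 genes called without it, and no called list or named gene was lost. The direction (for lists, that of camera) turned for 2 named genes and 4 lists, none of which had passed: Klf4 (-0.22 as deposited, -0.024 after centring on the median, -0.16 without WT clone 2, -0.070 without KO clone 2, and -0.16 to 0.32 over the leave-outs), Nanog after centring on pluripotency genes (0.059), the FGF and ERK list, whose medians were -0.13 with a pseudocount of 64, -0.14 with the stricter filter, -0.46 as deposited, -0.26 after centring on the median, -0.037 without WT clone 2 (-0.10 to 0.027 over the leave-outs) and -0.073 with the mean of a gene's probe sets, the interferon list (-0.16 with the stricter filter), the mesoderm list (-0.028 without WT clone 2, to 0.28) and the LIF list (0.048 without KO clone 1, from -0.18). Of the 60 named genes past the threshold other than Klf5, 34 no longer passed with a pseudocount of 1, 33 with no filter, 23 as deposited, and 15, 22, 32 and 25 without WT clone 1, WT clone 2, KO clone 1 and KO clone 2. Leaving out genes of the fibroblast and mesenchymal lists from the other lists left 10 lists past the threshold.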

Other observations

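Of the tests below, those on the scaling of the fibroblast genes, on WT clone 1 and on the ratio of rises of Otx2, Fgf5, Cdh2, Lefty1 and Lefty2 were chosen after their results were seen. On the list of cleavage-stage and germ cell genes, 3 of 21 rose, 1 fell and 17 did not pass (7 rose and 3 fell when adjusted over the list alone; median 0.21, camera, adjusted p = 0.13): Dazl, an RNA-binding protein of germ cells, rose by 1.10 ± 0.18 (adjusted p = 0.013, and 0.056 on its other probe set), Tex101, a germ cell surface protein, by 1.12 ± 0.23 (adjusted p = 0.035), and Prdm1, a regulator of primordial germ cells, fell by 1.09 ± 0.18 (adjusted p = 0.014). Each of these 3 calls was lost in 3 of the 4 leave-outs (highest adjusted p = 0.094, 0.15 and 0.11; Tex101 held without WT clone 2, Dazl and Prdm1 without WT clone 1). Of 3 measured Y-linked genes, Uba1y rose 3.08-fold (adjusted p = 0.0024) with intensities of 113 and 101 in WT and 329 and 398 in KO, Eif2s3y rose 1.78-fold (adjusted p = 0.047, and 0.085 to 0.24 with an array left out), and 1 did not pass (2 rose when adjusted over the list alone). Their median was 0.83 (camera, adjusted p = 0.0052, adjusted p = 0.45 with an estimated correlation and 0.12 with fry), beside 1.91 for fibroblast genes. Uba1y and Eif2s3y have close X-linked relatives, which can cross-hybridise.

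Of 27 imprinted genes, Ndn rose by 0.90 ± 0.18 (adjusted p = 0.028), Nnat fell by 1.36 ± 0.31 (adjusted p = 0.048), Peg10 fell and 24 did not pass (2 rose and 3 fell when adjusted over the list alone; median -0.040, camera, adjusted p = 0.25). Ndn failed with any array left out (highest adjusted p = 0.15) and on 2 of its 5 probe sets (adjusted p = 0.056 and 0.0998), and Nnat without WT clone 2 (0.17) or KO clone 1 (0.25). Meg3, Ascl2, Grb10 and Plagl1, named after their values were seen, differed between clones of 1 group, in KO and in WT. Grb10 read 400 in WT clone 1 against 101 in WT clone 2 and 171 and 253 in KO. Plagl1 read 665 in WT clone 1 against 273 in WT clone 2 and 410 and 421 in KO. Meg3 read 777 in KO clone 1 against 337 in KO clone 2 and 353 and 275 in WT. Ascl2 read 16.2 in KO clone 1 against 69.8 in KO clone 2 and 93.7 and 113 in WT. These were picked from the 27 for their large clone differences, so they do not show that imprinted genes differ more than other genes. Over all kept probe sets, the SD of the log2 difference between clones was 0.35 in KO and 0.32 in WT. Of 17 interferon response genes, B2m, a subunit of MHC class I, rose by 1.26 ± 0.20 (adjusted p = 0.011), Psmb8, an immunoproteasome subunit, by 0.80 ± 0.18 (adjusted p = 0.049), Ddx58 (the RNA sensor RIG-I) fell by 0.94 ± 0.18 (adjusted p = 0.024), and 14 did not pass (4 rose and 2 fell when adjusted over the list alone; median 0.068, camera, adjusted p = 0.61). Psmb8 and Ddx58 failed with any array left out (highest adjusted p = 0.16 and 0.14), and B2m in all leave-outs but that of WT clone 1 (highest adjusted p = 0.11). Of 20 cholesterol synthesis genes, Insig1, a sterol sensor, rose by 0.87 ± 0.19 (adjusted p = 0.042, and 0.081 to 0.22 with an array left out), and 19 did not pass, among them Sc5d at 0.60 ± 0.19 (1 rose when adjusted over the list alone). That list's median was 0.19 (camera, adjusted p = 0.027, and adjusted p = 0.45 with an estimated correlation), but -0.065 as deposited, with adjusted p = 0.25, 0.14 after centring on the median and 0.079 without WT clone 1. None of the 24 amino acid and unfolded protein stress genes, 25 glycolysis and hypoxia genes and 20 ribosomal protein genes passed by limma (7, 3 and 1 at an unadjusted p under 0.05; 2 higher and 3 lower, 0 and 0 when adjusted over the list alone). Their medians were -0.14, -0.13 and 0.021 (camera, adjusted p = 0.32, 0.35 and 0.35). The largest changes there were Chac1 at -0.92 ± 0.25 and Dnajb9 at 0.76 ± 0.18, Vegfa at 0.86 ± 0.20 and Pfkl at -0.67 ± 0.22, and Rps24 at 0.89 ± 0.38 and Rpl14 at 0.40 ± 0.18. KO clone 1 carries the value of Rps24 (0.19 without it, 1.603 without KO clone 2), and 4 brighter probe sets of Rps24 had log2 fold changes of 0.093 to 0.30. Without WT clone 2, Chac1 had -0.54 and Pfkl -0.41, and Pfkl had 0.38 on a dim probe set.

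The first pattern is the rise of fibroblast genes in both KO clones (26 of 27). The list's median was 1.77 or more under each of the 3 scalings. The median of all kept probe sets lay between -0.19 (as deposited) and 0.0055 (centred on the median) under them. The choice between these scalings was therefore too small to account for the rise. For the same reason the list could hardly have failed this comparison, so it is not an independent test. A candidate explanation is RNA of 1 kind of fibroblast-like cell in the KO samples, such as feeder cells carried over, although the labels name no feeder layer: such a source would raise all its genes in 1 ratio between the clones, and the spread of the log2 ratio of the rises (SD 0.31 over 26 genes) was 0.957 times that of unchanged probe sets between the KO clones (SD 0.33). The most abundant members rose to intensities of 3152 and 3527 (Acta2, named after its values were seen) in KO clones, and 6 of the 27 were above the median probe set in WT clones too, while 1 is also on the mesenchymal list. Expression by the KO cells themselves, after differentiation for example, cannot be told apart from added fibroblasts, since both would give 1 ratio and the one further marker chosen beforehand, H19, had 0 named probe sets.

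The second pattern is the set of 175 lower genes. The brightness of the WT clone 1 array was weighed as a cause. The number of probe sets called lower without that array was 1.06 times the number without WT clone 2. By the 2-fold criterion the order was reversed, with 108 lower without WT clone 1 and 162 without WT clone 2. The arrays had been quantile normalized, which evens out brightness, so neither comparison can test it. Against WT clone 2 alone, the 175 genes had a median of -0.997, beside -1.01 against both WT clones, in the arrays that chose them. Dilution of ES cell RNA by other cells may account for part of the falls: pluripotency genes fell by a median of 0.18, and the 23 dimmer ones by 0.31. The dimmer ones are those with a mean log2 value under 11. This limit leaves out Pou5f1, Sox2, Nanog and Klf4. It keeps Nr0b1 and Tcl1, which are themselves among the 175 lower genes. Once the arrays were centred on these 23, the median of the 175 genes went from -1.01 (median SE 0.19) to -0.78 (median SE 0.25), with quartiles of -0.99 and -0.65. Centring moved all 175 by the same 0.24, so the size of a fall and its error alone set which 81 stayed past the threshold (median -1.27 before and -1.03 after) and which 94 did not (median -0.90, SE 0.19 before, and -0.67, SE 0.25 after), and these are not 2 kinds of genes. All 175 stayed at an unadjusted p under 0.05, but they were chosen for their falls in the same arrays, so the part of dilution stays open. A response to loss of Klf5 is the biological explanation that the design names, and it is untested here beyond the comparison itself.

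The third pattern is the rise of Otx2, Fgf5, Cdh2, Lefty1 and Lefty2, for which fibroblast RNA was weighed as an explanation too. It would need fibroblasts that express these genes, and no array of fibroblasts alone was measured here. The ratio of the rise in KO clone 1 over that in KO clone 2 had a median of -0.46 (log2) over these 5 genes, from -0.60 to 0.36, against -0.017 for the fibroblast list. Of 65780 draws of 5 fibroblast genes, 0 had a median as far from the list's, which would hold against fibroblast RNA if the 5 genes varied no more than that list. Their own errors, propagated from the clone spread of unchanged probe sets, were 0.44 to 0.73 per gene, and against the resulting error of 0.35 the gap of 0.44 was 1.27 errors (for fibroblast genes, this error had a median of 0.44 per gene, above their observed SD of 0.31). With 5 genes chosen because they rose and the methods differing, fibroblast RNA and a shift of the KO cells towards an epiblast-like state cannot be told apart by this ratio.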
